A study of Homo sapiens with 24 samples.

How the data were processed

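Messenger RNA was measured in 4 bladder cancer cell lines (T24, 5637, TCC-SUP and CLS-439), each left untreated or treated with mitomycin C (MMC), a DNA crosslinking drug. Per the labels' protocols, cells received 75 µM MMC for 1 h and RNA was taken 15 h after treatment with a column kit and DNase, followed by a stranded poly(A) library kit. Each line has 3 untreated and 3 treated libraries, numbered 1, 3 and 4, which the series' design text calls biological replicates, so 24 libraries form 8 groups. The treatment tag of the treated samples is spelled MCC, and was read as MMC because the protocol and the design text name that drug alone.

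The authors deposited 1 table of raw read counts per Ensembl gene for all libraries, with no normalization. The submitters' processing notes name STAR 2.5.3a, featureCounts 1.6.2 and genome build GRCh38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so counts of near-identical copies, of overlapping genes and of antisense genes are uncertain. The table holds 58381 gene IDs, of which 58216 occur in GENCODE release 29, the source of the symbols, coordinates (GRCh38) and gene lengths used here. The 165 other IDs held 0.0072% of the reads. Library totals ranged from 13791428 to 28821665 counted reads.

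Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr with the group as factor were kept (20820 genes with 99.94% of the reads), libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 24 libraries with robust estimates (16 residual degrees of freedom, common dispersion 0.0317). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, with a second count at a log2 fold change of at least 1. The contrasts were treated against untreated in each line, the mean of the 4 responses, a test for any difference of response among the lines, the 6 differences between pairs of lines, and each untreated line against the mean of the others. Levels are CPM, the counts of a gene scaled to a common library size after TMM, with the SD over 3 libraries. Standard errors (SE) belong to log2 fold changes. All adjusted p values of genes come from this test.

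Gene lists (37) were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 37 lists in each contrast. The same test with a correlation estimated for each list is given as a second adjusted p. Of the 107 list calls with the preset value in the responses, their mean and the untreated comparisons, 29 held with the estimated correlation and 78 did not. List tests on the differences between pairs of lines were added after the data had been seen. Of the listed symbols, 3 had no match in the table. Some lists share members, so their results are not independent. The p53 target and pro-apoptotic lists both hold BBC3, BAX, FAS and TNFRSF10B. Genes to name were chosen by a rule fixed before the data were examined: in each line the 8 largest rises and the 8 largest falls among called genes with all treated libraries on the same side of all untreated ones, at least 10 CPM in the higher group and an ordinary symbol. The rule took 10 each way for the mean response (called in the same direction in every line, which left 8 rises), the 10 smallest p for differing responses, and 6 for each untreated line. The rule also asked for 11 genes in every line and for the called members of each list with the largest changes. Any list member could be named. Not all of these genes are given below, and a list member named there need not be the one that changed most. For untreated T24 and CLS-439, 1 gene each was left out because its level is not printed here. Some genes that the rule or the lists would name are not reported here.

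Replicates were compared before averaging. The lowest chi-square per gene between 2 libraries of a group was 4.15, so none agreed within sampling noise. Whether replicate numbers pair the libraries was checked by correlating the deviations of same-numbered treated and untreated libraries from their group means. The correlation was above 0.1 for every number in 5637 (0.35, 0.19 and 0.52) and CLS-439 (0.39, 0.30 and 0.13), where the numbers were taken as pairs. Numbers in T24 and TCC-SUP were not. Deviations from a group mean are tied to each other, so the correlations of a line are not independent checks of pairing. The main fit uses no pairs in any line, so its p values and counts ignore any such pairing, which only the replicate block uses.

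Counts were simulated from the real untreated means and library sizes (20210 genes), with known changes planted only in genes at a mean of 10 CPM or more. There edgeR recovered 86% of genes changed 2-fold and 98.5% of those changed 4-fold in T24. The shares were 74% and 96% in 5637, 83% and 97% in TCC-SUP, 76% and 93% in CLS-439, and 51% and 97% for differing responses. These shares do not cover genes at lower levels. The simulated noise was independent between libraries, unlike that of the real same-numbered treated libraries. Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a fold minimum, a replicate block, fits of a single line, leaving out each library in turn, for lists an estimated correlation and fry, and for lists and correlations leaving out each replicate number from all groups. Leaving out a replicate number for counts of called genes was added after the data had been seen, because treated replicate 1 stood apart in 3 lines. Settings without the CLS-439 libraries, and counts of genes shared by lines under each setting, were also added after the data had been seen. No library or gene other than those named was left out.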

Results

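The series, given as human, asked how 4 bladder cancer cell lines change their gene expression after mitomycin C, a drug used against bladder cancer that crosslinks DNA strands. T24, 5637, TCC-SUP and CLS-439 cells were compared with and without the drug, with 3 libraries in each of the 8 groups. Whether the RNA of CLS-439 matches the human reference stays open, which bears on every result with this line. Counted reads per library lay between 19550429 and 28821665 in T24, 19384501 and 23810260 in 5637, 20748210 and 23728382 in TCC-SUP, and 13791428 and 20863429 in CLS-439. Of 20820 genes tested, MMC changed 5947 in T24, 6128 in 5637, 4306 in TCC-SUP and 129 in CLS-439. Changes called largest are the largest among genes at 10 CPM or more in the higher group with no overlap between the libraries compared.

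**Figure D1:**
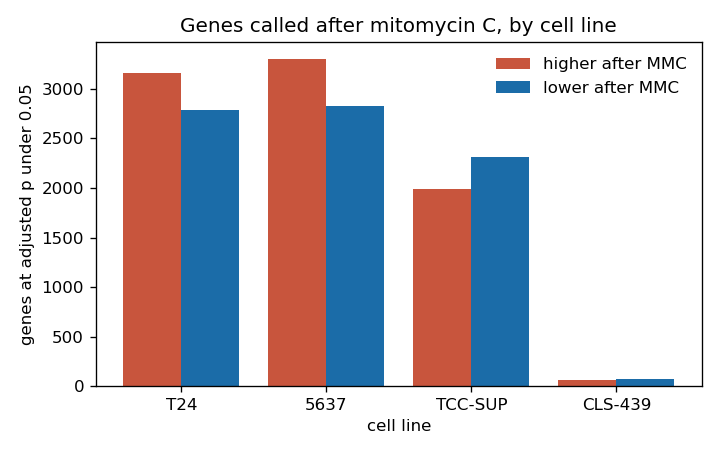
Bars give the number of genes called higher or lower after MMC (y axis, genes at an adjusted p under 0.05) in each cell line (x axis), from 3 treated and 3 untreated libraries per line. CLS-439 has 62 higher and 67 lower genes, against 1993 or more in each direction in the other lines.

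The first comparison asks what MMC changed in T24. Inflammatory genes led the rises. IL6, an inflammatory cytokine (chromosome 7, 22725884 to 22732002), went from 4.21 ± 0.187 to 276 ± 33.4 CPM (SD, n = 3), a log2 fold change of 6.03 (SE 0.39, adjusted p = 1.17e-10). ATF3, a stress-induced transcription factor, rose by 5.59 (SE 0.33), TRAF1 by 5.12 (SE 0.31), PTGS2, which encodes cyclooxygenase 2, by 4.81 (SE 0.33), and the NF-kB genes RELB and TNFAIP3 by 4.39 (SE 0.22) and 4.38 (SE 0.28). RND1 and VASN completed the 8 largest rises, at 4.48 and 4.26. The largest falls were in CDH4, a cadherin (chromosome 20, 61252426 to 61940617), from 55.1 ± 9.58 to 4.10 ± 0.895 CPM (log2 fold change -3.75, SE 0.23, adjusted p = 1.17e-10), and in NEGR1, PTPRG, RIMS1, ARL15, PSD3, SBF2 and GMDS, with log2 fold changes from -3.70 to -2.72. By the rule that chose these 16 genes, all 3 treated libraries lay on the same side of all untreated ones.

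Among the gene lists, 21 of 24 NF-kB and cytokine genes rose in T24 and 1 fell (camera adjusted p = 7.11e-29). The call held at an adjusted p = 0.0108 with an estimated correlation. The falling member was CSF3 (log2 fold change -1.67, SE 0.49), and CXCL8 rose by 2.59 (SE 0.36). Integrated stress response genes rose in 15 of 18 cases (5.68e-16, and adjusted p = 0.0108 with an estimated correlation), among them DDIT3 by 2.89 and CHAC1 by 3.48. Immediate-early and AP-1 genes rose in 18 of 21 (2.03e-14, and adjusted p = 0.0268 with an estimated correlation). Of p53 target genes, 15 of 32 rose and 3 fell (0.00109, and adjusted p = 0.0367 with an estimated correlation). CDKN1A, which blocks the cell cycle, rose by 2.59 (SE 0.21) and PLK2 fell by 0.60 on the log2 scale, while MDM2 had a log2 fold change of 0.38 (SE 0.15, adjusted p = 0.060). Pro-apoptotic regulators rose in 7 of 18 (0.00569, and adjusted p = 0.0268 with an estimated correlation), and cholesterol synthesis genes fell in 11 of 21 (4.86e-06, and adjusted p = 0.0268 with an estimated correlation), INSIG1 by 1.55 on the log2 scale.

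Other list calls in T24 were lost when the correlation was estimated. Interferon-stimulated genes rose in 21 of 27 (camera adjusted p = 2.04e-07, adjusted p = 0.33 with an estimated correlation), with MX1 at 2.75 (SE 0.39). MHC class I genes rose in 11 of 15 (2.36e-05, adjusted p = 0.204 with an estimated correlation), with HLA-B at 1.23. G2 and mitosis genes fell in 15 of 28 and 1 rose (7.3e-10, adjusted p = 0.117 with an estimated correlation), with PLK1 at -1.74 (SE 0.14) and CCNB1 at -1.51 (SE 0.14). The remaining calls covered nucleic acid sensing (5 of 12 higher, 0.018, adjusted p = 0.223 with an estimated correlation) and NK and checkpoint ligands (6 of 14 higher and 2 lower, 0.0209, adjusted p = 0.0914 with an estimated correlation). Mitochondrially encoded transcripts (4 of 13 lower, 0.00265, adjusted p = 0.33 with an estimated correlation) and heat shock genes (5 of 13 lower, 0.0209, adjusted p = 0.223 with an estimated correlation) went down. Adjusted over the list alone and counted in the direction of each list, 21 NF-kB, 16 stress response, 19 AP-1, 16 p53 target, 8 pro-apoptotic, 22 interferon-stimulated, 11 MHC class I, 5 sensing and 7 ligand genes rose, and 16 mitotic, 16 cholesterol synthesis, 7 mitochondrially encoded and 5 heat shock genes fell.

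MMC changed 5947 genes in T24, 3162 higher and 2785 lower, of which 1533 and 1090 changed at least by a log2 value of 1. Fitted without the other lines, T24 gave 1907 higher and 1663 lower. It gave 1691 and 1771 without replicate 3 of all groups and 820 and 753 without replicate 4.

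The second comparison covers 5637. The largest rises were in SERPINB10, a serpin, from 0.181 ± 0.158 to 16.2 ± 15.3 CPM (log2 fold change 6.46, SE 1.35, adjusted p = 0.0018), TEX14 (4.78, SE 0.57), VASN (4.48, SE 0.57), SNAI1, a transcription factor of epithelial to mesenchymal change (4.35, SE 0.46), and ATF3 (4.33, SE 0.31). HAP1, FOSB and IL6 followed at 4.28, 4.23 and 3.89. CDH4 fell from 26.6 ± 0.585 to 0.852 ± 0.0086 CPM (log2 fold change -4.96, SE 0.27, adjusted p = 4.61e-11). NCKAP5, XYLT1, TENM2, THSD7B, DSCAM and SDK1 fell with log2 values from -4.63 to -3.52.

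Genes of G1/S and DNA replication rose in 16 of 25 cases in 5637 with no fall (camera adjusted p = 1.28e-08, and adjusted p = 0.031 with an estimated correlation), including MCM2, a replicative helicase subunit, by 1.06 (SE 0.12) and CCNE2 by 1.51 (SE 0.21). Cholesterol synthesis genes fell in 13 of 21 (1.16e-06, and adjusted p = 0.031 with an estimated correlation). Pro-apoptotic regulators rose in 9 of 18 (0.000114, and adjusted p = 0.0118 with an estimated correlation), p53 target genes in 10 of 32 with 1 fall (0.00024, and adjusted p = 0.0352 with an estimated correlation), and NK and checkpoint ligands in 8 of 14 (0.00363, and adjusted p = 0.0439 with an estimated correlation). CD274, which encodes PD-L1, rose by 1.39 (SE 0.23), and the NKG2D ligand MICB rose by 1.66 (SE 0.18). NF-kB and cytokine genes rose in 18 of 24 with 1 fall (1.21e-09, adjusted p = 0.104 with an estimated correlation), AP-1 genes in 15 of 21 with 1 fall (2.37e-07, adjusted p = 0.113 with an estimated correlation), and stress response genes in 10 of 18 with 2 falls (0.000181, adjusted p = 0.187 with an estimated correlation).

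Ribosomal protein genes fell in 41 of 76 cases in 5637 with a median log2 fold change of -0.40 (4.69e-12, adjusted p = 0.456 with an estimated correlation). G2 and mitosis genes fell in 15 of 28 and 2 rose (1.16e-06, adjusted p = 0.204 with an estimated correlation). CDK1, the mitotic kinase, rose by 0.43 (SE 0.14), whereas CCNB1 fell by 1.36 on the log2 scale. Unfolded protein response genes fell in 10 of 16 and 1 rose (2.85e-05, adjusted p = 0.0808 with an estimated correlation), with the chaperone HSPA5 going from 1573 to 380 CPM. Basal urothelial genes fell in 7 of 18 and 1 rose (0.00252, adjusted p = 0.187 with an estimated correlation), KRT5 by 1.27 on the log2 scale. Danger signals (5 of 12 lower, 0.014, adjusted p = 0.101 with an estimated correlation) and respiratory complexes II to V (8 of 38 lower and 1 higher, 0.0164, adjusted p = 0.861 with an estimated correlation) also went down. Mitochondrial biogenesis genes (7 of 16 lower and 2 higher, 0.0494, adjusted p = 0.166 with an estimated correlation) lost their call with the replicate block (0.0758) and without the CLS-439 libraries (0.0726). Adjusted over the list alone and counted in the direction of each list, 17 G1/S, 9 pro-apoptotic, 15 p53 target, 8 ligand, 20 NF-kB, 17 AP-1 and 10 stress response genes rose, and 14 cholesterol synthesis, 47 ribosomal, 15 mitotic, 10 unfolded protein response, 8 basal, 6 danger signal, 8 respiratory and 7 mitochondrial biogenesis genes fell.

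In all, 3305 genes rose and 2823 fell, 1779 and 1251 of them at least by a log2 value of 1. With the replicate block, 3503 rose and 3232 fell. The counts were 1504 and 1369 without replicate 3 of all groups and 1017 and 875 without replicate 4.

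The third comparison covers TCC-SUP. LRRC4 rose from 2.53 ± 1.35 to 22.7 ± 9.14 CPM (log2 fold change 3.17, SE 0.47, adjusted p = 8.19e-05). FOSB rose by 3.01 (SE 0.35), HBEGF, a ligand of the EGF receptor, by 2.83 (SE 0.28), IL11 by 2.26 (SE 0.33), SAT1 by 2.25 (SE 0.24), ATF3 by 2.25 (SE 0.28), and ERFE and SELPLG by 1.87 and 1.83. The histone deacetylase gene HDAC4 fell from 16.8 ± 1.06 to 1.11 ± 0.711 CPM (log2 fold change -3.94, SE 0.60, adjusted p = 0.000141). SNX29, BTBD9, ANK3, ST6GALNAC3, PARD3B, TSHZ2 and FRMPD4 fell with log2 values from -3.66 to -3.27.

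In TCC-SUP every list call was lost with an estimated correlation. NF-kB and cytokine genes rose in 13 of 24 cases (camera adjusted p = 2.45e-07, adjusted p = 0.143 with an estimated correlation), with ICAM1 at 0.69 (SE 0.22). G1/S and DNA replication genes rose in 14 of 25 and 2 fell (1.49e-06, adjusted p = 0.0786 with an estimated correlation), E2F1 by 1.06. AP-1 genes (8 of 21 higher, 0.000184, adjusted p = 0.29 with an estimated correlation), p53 target genes (10 of 32 higher, 0.00599, adjusted p = 0.099 with an estimated correlation), NK and checkpoint ligands (6 of 14 higher, 0.0106, adjusted p = 0.0786 with an estimated correlation) and pro-apoptotic regulators (6 of 18 higher, 0.0191, adjusted p = 0.0786 with an estimated correlation) went up. Unfolded protein response genes fell in 10 of 16 (1.75e-06, adjusted p = 0.0786 with an estimated correlation), HSPA5 by 1.43 on the log2 scale, and NRF2 targets in 9 of 18 (0.000351, adjusted p = 0.13 with an estimated correlation), HMOX1 by 1.12 on the log2 scale. Mesenchymal and matrix genes (7 of 21 lower, 0.00101, adjusted p = 0.0786 with an estimated correlation), fibroblast markers (3 of 9 lower, 0.0249, adjusted p = 0.13 with an estimated correlation), ribosomal protein genes (6 of 76 lower, 0.00116, adjusted p = 0.817 with an estimated correlation), G2 and mitosis genes (6 of 28 lower, 0.0165, adjusted p = 0.669 with an estimated correlation) and MMC-reducing enzymes and efflux pumps (3 of 10 lower, 0.0317, adjusted p = 0.099 with an estimated correlation) went down, the last without a call when the CLS-439 libraries were left out (0.0528). COL1A1 fell from 4298 to 2401 CPM, and NQO1, an MMC-reducing enzyme, fell from 1027 to 650 CPM. Adjusted over the list alone and counted in the direction of each list, 13 NF-kB, 15 G1/S, 8 AP-1, 11 p53 target, 6 ligand and 6 pro-apoptotic genes rose, and 12 unfolded protein response, 10 NRF2, 11 mesenchymal, 3 fibroblast, 5 ribosomal, 6 mitotic and 3 MMC-reducing or efflux genes fell.

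In all, 1993 genes rose and 2313 fell, 710 and 1135 of them at least by a log2 value of 1. Leaving out 1 library gave 954 rises and 1255 falls without treated replicate 3, and 1192, 1266 and 1268 rises without untreated replicates 1, 3 and 4. The counts were 350 and 834 without replicate 3 of all groups and 100 and 173 without replicate 4.

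In CLS-439, the fourth comparison, p53 target genes led the rises. CDKN1A went from 78.4 ± 10.6 to 470 ± 155 CPM (log2 fold change 2.58, SE 0.21, adjusted p = 1.4e-07). The death receptor gene FAS rose by 1.98 (SE 0.23, adjusted p = 3.26e-05), MDM2, which encodes the ubiquitin ligase of p53, by 1.53 (SE 0.15, adjusted p = 4.35e-06), and RRM2B by 1.29 (SE 0.23). ACER2, CDC42BPG, F3 and EDA2R rose by 1.62, 1.55, 1.54 and 1.38. TENM4 (-2.02, SE 0.35), the histone gene H2AC6 (-1.88, SE 0.27), SORCS2, CYP24A1, TRAPPC9, SLIT3 and IGFBP5 fell, the last at -1.51.

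Of 32 p53 target genes tested in CLS-439, 11 rose, and 21 rose when adjusted over the list alone (camera adjusted p = 1.15e-35, and adjusted p = 4.8e-07 with an estimated correlation). Pro-apoptotic regulators rose in 3 of 18 cases, 5 when adjusted over the list alone (2.61e-06, and adjusted p = 0.000804 with an estimated correlation). Of the 3, FAS and TNFRSF10B are also in the p53 target list, so the calls of these lists are not independent. G2 and mitosis genes fell in 7 of 28, 10 when adjusted over the list alone (1.32e-17, and adjusted p = 0.0419 with an estimated correlation), with CDC20 at -1.23 (SE 0.15) and CCNB1 at -1.01 (SE 0.13). Histone genes fell in 3 of 17, 5 when adjusted over the list alone (8.82e-11, and adjusted p = 0.0419 with an estimated correlation). The 76 ribosomal protein genes were shifted down with a median of -0.14 and no single call by edgeR (1.07e-05, adjusted p = 0.867 with an estimated correlation). Stress response genes (2 of 18 higher and 1 lower adjusted over the list alone, 0.0231, adjusted p = 0.609 with an estimated correlation), NK and checkpoint ligands (1 of 14 higher adjusted over the list alone, 0.0238, adjusted p = 0.112 with an estimated correlation) and AP-1 genes (1 of 21 higher, 0.0238, adjusted p = 0.704 with an estimated correlation) were shifted up. So were anti-apoptotic regulators (1 of 9 higher adjusted over the list alone, 0.0422, adjusted p = 0.274 with an estimated correlation), whose median was 0.23 and mean -0.01. With the replicate block, 3 more lists passed the threshold, nucleotide excision repair (up, 0.042), the unfolded protein response (down, 0.0466) and respiratory complexes II to V (down, 0.042).

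In all, 62 genes rose and 67 fell in CLS-439, 46 and 41 of them at least by a log2 value of 1. The replicate block gave 75 rises and 113 falls. At an unadjusted p under 0.05 there were 1623 genes. Fitted alone, CLS-439 gave 292 rises and 381 falls, DESeq2 gave 119 and 157, and the fit with no filter 116 and 216. Leaving out untreated replicates 1, 3 and 4 gave 24, 21 and 19 rises and 28, 31 and 32 falls, and leaving out treated replicates 3 and 4 gave 38 and 17 rises and 24 and 22 falls. Without replicates 1, 3 and 4 of all groups in turn, edgeR called 109, 9 and 3 rises and 192, 8 and 0 falls, and the last setting had 436 falls at an unadjusted p under 0.05, with no other tool run. Mitochondrially encoded genes held 0.0238% to 0.0283% of the reads in the 6 CLS-439 libraries and 3.21% to 7.40% in the other 18, and processed pseudogenes held 2.75% to 3.05% against at most 0.229%.

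**Figure D2:**
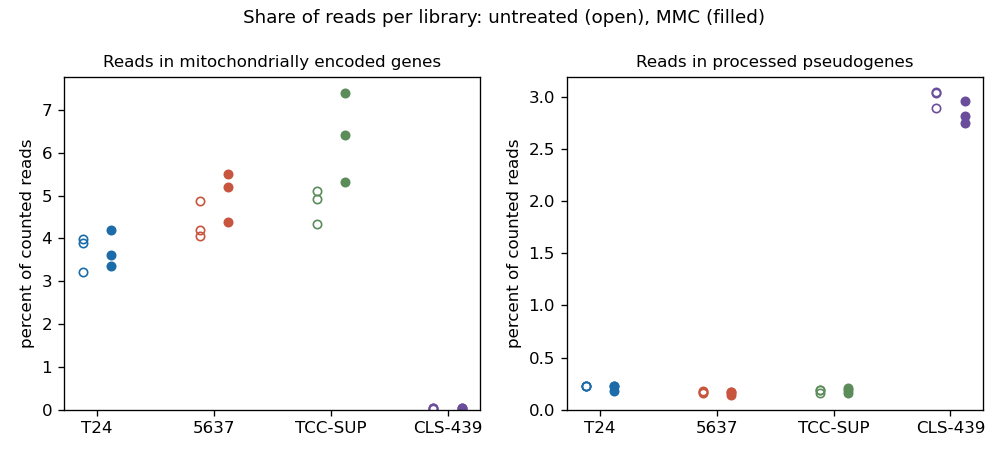
Percent of counted reads (y axes) in mitochondrially encoded genes (left) and processed pseudogenes (right) per library in the 4 cell lines (x axes), with open circles for untreated and filled circles for treated libraries. The 6 CLS-439 libraries lie at 0.0238% to 0.0283% on the left and at 2.75% to 3.05% on the right, and the other 18 at 3.21% or more and at most 0.229%.

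**Figure D3:**
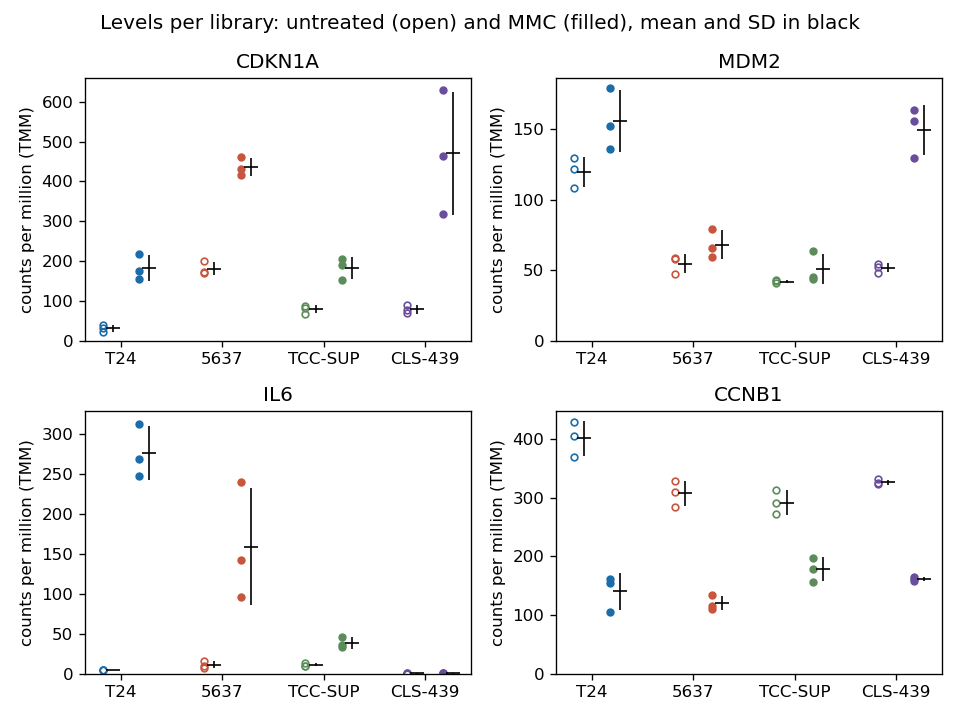
Levels (y axes, CPM after TMM) of CDKN1A, MDM2, IL6 and CCNB1 in the 4 cell lines (x axes), with open circles for untreated and filled circles for treated libraries and black marks for the mean and SD of 3 libraries. MDM2 reaches a mean of 150 CPM in treated CLS-439 from 51.6 CPM untreated, and IL6 reaches 276 CPM in treated T24.

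The mean response over the 4 lines is their average, so a gene or list called in it need not respond in every line. What the lines had in common was counted apart, from calls in the same direction in every line. The test of the mean response treats all libraries as independent. Same-numbered treated libraries of T24, 5637 and TCC-SUP deviated together, however (correlations from 0.21 to 0.69). The SE and p values of the mean response may therefore be too small, and its counts of calls too high. Genes called in the same direction in every line numbered 11 higher and 22 lower. Of the 11, TRAF1 had a mean rise of 2.76 (SE 0.17), but its CLS-439 libraries overlapped and lay near 1 CPM. Among those without such overlap and at a treated mean of 10 CPM or more over the lines, CDKN1A had the largest mean rise (1.91, SE 0.10, adjusted p = 2.47e-12), followed by MAFF (1.54, SE 0.10), CYP26B1 (1.40), PLCXD2 (1.25), BRME1 (1.21), RNF19B (0.75), the death receptor gene TNFRSF10B (0.64) and SNRNP27 (0.46). TRAPPC9 (-2.30, SE 0.15), GTDC1 (-2.22), GALNT18 (-2.05), FAR2 (-1.95), STX8 (-1.83), IGFBP5 (-1.82), MAD1L1 (-1.77), DOCK2 (-1.47), COL18A1 (-1.38) and PIF1 (-1.34) had the largest mean falls at an untreated mean of 10 CPM or more over the lines, and PARD3B, under that level, had -3.49 (SE 0.28). The mitotic genes CCNB1, PLK1, CDC20, AURKA and KIF20A were also lower in every line. In T24, 5637 and TCC-SUP together, 851 genes were higher and 880 lower, against 48 and 42 for independent lists drawn from all genes tested. That reference ignores how well each gene can be called and the shared deviations of same-numbered treated libraries, so it sets no chance level. The 851 higher genes became 498 without treated TCC-SUP replicate 3 and 558 without untreated TCC-SUP replicate 3. Without replicate 4 of all groups the counts were 47 and 69, and no reference was computed for those shorter lists. Across genes, which are not independent replicates, Pearson's r of the responses was 0.48 for T24 and 5637, 0.40 for T24 and TCC-SUP, 0.45 for 5637 and TCC-SUP, and 0.11 to 0.15 for CLS-439 with each other line. At genes of 10 CPM or more these values were 0.647, 0.566, 0.666 and 0.199 to 0.291. With no filter they were 0.306, 0.24, 0.282 and 0.042 to 0.057. Leaving out single libraries moved the 11 shared rises to between 1 (without treated CLS-439 replicate 4) and 20 (without treated T24 replicate 1). The 22 shared falls moved to between 6 (without treated CLS-439 replicate 3) and 57 (without treated T24 replicate 1). Without replicates 1, 3 and 4 of all groups in turn, there were 26, 1 and 1 shared rises and 93, 2 and 0 shared falls.

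Over the mean response, 3986 genes rose and 3628 fell, 846 and 608 at least by a log2 value of 1, and the counts were 2165 and 2284 without replicate 3 of all groups and 1947 and 2048 without replicate 4. List calls that held with an estimated correlation were p53 target genes (21 of 32 higher and 2 lower, camera adjusted p = 1.73e-09, and adjusted p = 0.00115 with an estimated correlation), pro-apoptotic regulators (12 of 18 higher, 3.06e-06, and adjusted p = 0.00115 with an estimated correlation), NK and checkpoint ligands (8 of 14 higher and 1 lower, 0.000252, and adjusted p = 0.019 with an estimated correlation), and NF-kB genes, AP-1 genes and G1/S genes. Of these, 17 of 24, 18 of 21 and 16 of 25 rose and 0, 1 and 2 fell (2.22e-13, 1.25e-11 and 1.13e-06, each with an adjusted p = 0.0464 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 21 (8.82e-06, and adjusted p = 0.0464 with an estimated correlation). The p53 target and pro-apoptotic lists share members, so their calls are not independent. Calls lost with an estimated correlation were falls of G2 and mitosis genes (20 of 28 lower and 1 higher, 4.2e-11, adjusted p = 0.0715 with an estimated correlation), unfolded protein response genes (8 of 16, 3.37e-05, adjusted p = 0.0679 with an estimated correlation) and ribosomal protein genes (39 of 76, 1.79e-09, adjusted p = 0.595 with an estimated correlation). Rises lost in the same way were those of stress response genes (11 of 18, 1.51e-06, adjusted p = 0.0715 with an estimated correlation), interferon-stimulated genes (12 of 27, 0.00238, adjusted p = 0.672 with an estimated correlation) and MHC class I genes (7 of 15, 0.0073, adjusted p = 0.515 with an estimated correlation). Adjusted over the list alone and counted in the direction of each list, 22 p53 target, 12 pro-apoptotic, 8 ligand, 18 NF-kB, 18 AP-1, 18 G1/S, 11 stress response, 13 interferon-stimulated and 7 MHC class I genes rose, and 15 cholesterol synthesis, 20 mitotic, 9 unfolded protein response and 39 ribosomal genes fell.

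Lists whose response passed in no line and not in the mean were Fanconi and crosslink repair (lowest adjusted p 0.0937, in 5637), nucleotide excision repair (0.0568, in CLS-439, where the replicate block gave 0.042), inflammasome and pyroptosis (0.345, in CLS-439), the APOBEC3 family (0.0817, in CLS-439), respiratory complex I (0.0905, in CLS-439), hypoxia and glycolysis (0.243, in TCC-SUP), epithelial genes (0.225, in T24), luminal urothelial genes (0.874, in CLS-439), neuroendocrine genes (0.12, in TCC-SUP), and blood and endothelial markers (0.719 and 0.458, both in TCC-SUP).

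Genes called lower after MMC had longer genomic spans than those called higher. The median span was 59.6 kb for lower and 17.6 kb for higher genes in T24, 71.7 and 15.1 kb in 5637, 130.2 and 14.3 kb in TCC-SUP, and 29.5 and 25.5 kb in CLS-439. Across 20792 genes, which are not independent replicates, Spearman's rho of log2 fold change with span was -0.161 in T24, -0.227 in 5637, -0.302 in TCC-SUP and -0.006 in CLS-439. After the ranks of exon length, GC content and expression level were removed, rho was -0.089, -0.134, -0.256 and -0.091.

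**Figure D4:**
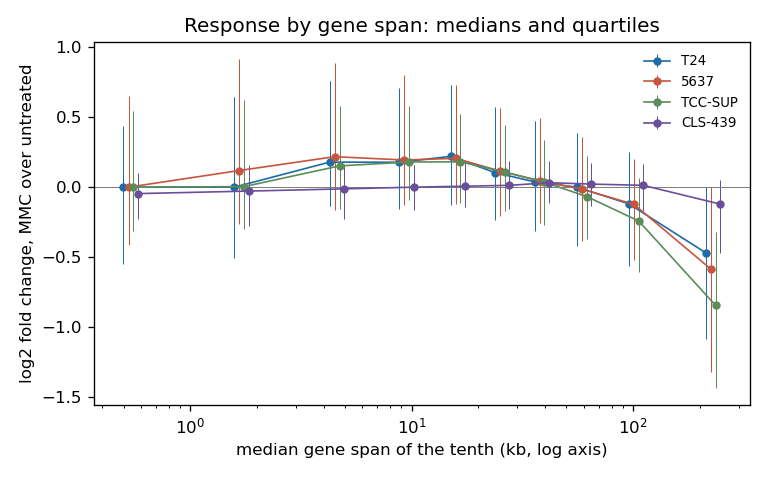
Median log2 fold change after MMC (y axis, points, with bars from the lower to the upper quartile over genes) in 10 equal groups of genes ordered by genomic span (x axis, median span of the group in kb, log scale), for the 4 cell lines. In the group with the longest spans (median 230.25 kb) the medians are -0.47 in T24, -0.58 in 5637, -0.84 in TCC-SUP and -0.12 in CLS-439.

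Whether the response itself differed among lines was tested directly, and 3339 genes did. RELB rose by 4.39 in T24, 0.87 in 5637, 1.36 in TCC-SUP and had 0.20 in CLS-439 (SE 0.22, 0.18, 0.20 and 0.20). The phosphatase gene DUSP10 and the adhesion scaffold gene NEDD9 rose in T24 alone among the lines (3.42, SE 0.20, and 3.97, SE 0.26), and their T24 responses exceeded each of the others by 3.21 or more and 3.39 or more. DDIT3, which encodes the stress factor CHOP, rose by 2.89 in T24 and 1.96 in 5637, with 0.23 in TCC-SUP and 0.05 in CLS-439. The amino acid transporter gene SLC1A4 rose most in 5637 (2.37, SE 0.14). GADD45A, RND1, PPP1R15A, ATF3 and NFKB2 completed the 10 smallest p values. MDM2 rose in CLS-439 by more than in T24 (difference -1.16, SE 0.21, adjusted p = 0.00121), 5637 (adjusted p = 0.000713) and TCC-SUP (adjusted p = 0.00396), and FAS likewise (T24 minus CLS-439 -2.32, SE 0.30). CDK1 fell in T24 (-0.45) and rose in 5637 (0.43), a difference of -0.88 (SE 0.19, adjusted p = 0.00956).

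Between pairs of lines, 722 genes differed for T24 and 5637, 790 for T24 and TCC-SUP, 2110 for T24 and CLS-439, 562 for 5637 and TCC-SUP, 1878 for 5637 and CLS-439 and 551 for TCC-SUP and CLS-439. Leaving out 1 library moved these counts to between 402 (without untreated 5637 replicate 1) and 1138 (treated T24 replicate 1), 360 (untreated TCC-SUP replicate 4) and 1099 (treated T24 replicate 1), 1336 (untreated T24 replicate 4) and 3063 (treated T24 replicate 1), 302 (untreated 5637 replicate 3) and 849 (treated T24 replicate 1), 1192 (treated 5637 replicate 3) and 2829 (treated 5637 replicate 1), and 114 (treated TCC-SUP replicate 3) and 1409 (treated TCC-SUP replicate 1). In list tests added after the data had been seen, stress response genes rose more in T24 than in TCC-SUP in 16 of 18 cases (6.81e-36, and adjusted p = 0.000357 with an estimated correlation), NF-kB genes in 14 of 24 (1.57e-27, and adjusted p = 0.00853 with an estimated correlation). Against CLS-439, T24 had higher responses in 15 of 24 NF-kB genes (1.81e-25, and adjusted p = 0.0119 with an estimated correlation), and 5637 in 11 of 25 G1/S genes (1.03e-09, and adjusted p = 0.0301 with an estimated correlation). Adjusted over the list alone, these counts were 17, 20, 21 and 14. Without the CLS-439 libraries, a setting added after the data had been seen, 937 genes differed among the other lines. Without replicates 1, 3 and 4 of all groups in turn, 5085, 635 and 94 differed.

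The last comparison set each untreated line against the mean of the others. Untreated 5637 cells held epithelial transcripts that were near 0 elsewhere. KRT5, a basal keratin, stood at 1184 ± 72.3 CPM against a mean of 0.286 CPM in the other lines, GRHL2, an epithelial transcription factor, at 95.6 ± 3.96 against 0 CPM, and TP63 at 122 ± 6.37 against 0.774 CPM. LHFPL4, DAPP1, GJB6 and CALB1 were the other genes with the largest excess, at 48.8, 48.0, 37.7 and 211 CPM. Epithelial genes were higher in 14 of 15 cases (camera adjusted p = 6.63e-14, and adjusted p = 0.0223 with an estimated correlation) and basal urothelial genes in 17 of 18, with KRT14 lower (1.7e-14, and adjusted p = 0.0107 with an estimated correlation). NF-kB genes were higher in 19 of 24 and lower in 1 (4.65e-10, adjusted p = 0.228 with an estimated correlation), IL1A at 773 ± 83.5 CPM. Interferon-stimulated genes were lower in 20 of 27 and higher in 3 (3.03e-06, adjusted p = 0.452 with an estimated correlation).

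Untreated TCC-SUP cells held transcripts of matrix and fibroblast genes. COL1A2, a type I collagen chain, stood at 4120 ± 651 CPM against 0.0818 CPM, CD36 at 847 ± 215, A2M at 607 ± 141, LUM at 545 ± 280, DCN at 283 ± 119 and VCAM1 at 108 ± 4.60 CPM. All 9 fibroblast markers were higher (7.27e-10, and adjusted p = 0.00809 with an estimated correlation), as were 13 of 21 mesenchymal genes with 5 lower (0.00277, adjusted p = 0.148 with an estimated correlation). Among the lower was VIM, an intermediate filament gene, at 10.2 CPM against 745 CPM. Interferon-stimulated genes were higher in 26 of 27 (6.29e-12, adjusted p = 0.227 with an estimated correlation), MX1 at 326 ± 216 against 15.1 CPM. MHC class I genes were higher in 13 of 15 and lower in 1 (3.58e-06, adjusted p = 0.156 with an estimated correlation). Neuroendocrine genes were higher in 6 of 7 (0.00096, adjusted p = 0.11 with an estimated correlation).

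Untreated T24 was highest for HLA-DPB1 (31.3 ± 3.20 against 0.0404 CPM), WSCD1 (154 ± 31.3 against 3.25 CPM), BNC1 (166 ± 22.6 against 0.191 CPM), SHISA3 and LY6K. Inflammasome genes were higher in 10 of 15 cases and lower in 1 (0.000415, and adjusted p = 0.0396 with an estimated correlation), NLRP1 at 89.3 ± 7.71 CPM. Without the CLS-439 libraries, a setting added after the data had been seen, that call was lost (camera adjusted p = 0.431). Untreated CLS-439 was highest for PGR, which encodes the progesterone receptor (226 ± 16.0 against 0.00539 CPM), BEX1 (82.0 ± 2.79), NAT16 (50.5 ± 11.1) and COL11A1 (309 ± 44.1 CPM). Counts in CLS-439 depend on how well its reads matched the human reference, which the counts leave open, so lower values in this line are lower counts and need not be lower RNA levels. All 13 mitochondrially encoded genes had lower counts in CLS-439 (4.57e-15, adjusted p = 0.0694 with an estimated correlation), with MT-CO1, a subunit of cytochrome c oxidase, at 6.20 ± 1.74 CPM against 10600 CPM. Ribosomal protein genes (51 of 76 lower and 3 higher, 1.03e-06, adjusted p = 0.721 with an estimated correlation), NF-kB genes (17 of 24 lower and 1 higher, 6.81e-05, adjusted p = 0.561 with an estimated correlation) and inflammasome genes (13 of 15 lower and 2 higher, 0.000862, adjusted p = 0.0694 with an estimated correlation) had lower counts too. Adjusted over the list alone, the list counts given here for the untreated lines were the same, except for 20 higher NF-kB genes in 5637 and 11 higher inflammasome genes in T24. The counts of higher and lower genes were 5799 and 4748 in T24, 6776 and 5092 in 5637, 7332 and 5430 in TCC-SUP, and 8410 and 7125 in CLS-439. With DESeq2 they were 5497 and 6161 in T24, where the majority turned, and 6425 and 6230 in 5637. At a log2 fold change of at least 1 the majority turned in T24 as well, with 2812 higher and 3066 lower genes.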

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

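The list tests on differences between lines, the counts of other splits and all tests of technical explanations were chosen after the results were seen, except the test of gene span, whose bounds were set before the data were examined.

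The results below drew attention because the response to MMC differed between cell lines in a direct test of the difference (edgeR, Benjamini-Hochberg). Among the 4 lines 3339 genes differed, with RELB and DUSP10 at an adjusted p = 1.3e-08, DDIT3 and SLC1A4 at 1.42e-08, GADD45A at 2.71e-08, RND1 at 4.33e-08, NEDD9 at 7.76e-08, PPP1R15A at 1.54e-07, ATF3 at 1.87e-07 and NFKB2 at 2.53e-07. Of the other genes that the naming rule asked for in every line, FAS (8.51e-05), MDM2 (0.000438), CDKN1A (0.00064), IL1B (0.00357), POR (0.00462), CDK1 (0.00915), GDF15 (0.0115), CCNB1 (0.015) and CXCL8 (0.0455) differed, and NQO1 did not pass. Between pairs of lines, 722 genes differed for T24 and 5637, 790 for T24 and TCC-SUP, 2110 for T24 and CLS-439, 562 for 5637 and TCC-SUP, 1878 for 5637 and CLS-439, and 551 for TCC-SUP and CLS-439. Single libraries moved these counts to 402 to 1138, 360 to 1099, 1336 to 3063, 302 to 849, 1192 to 2829 and 114 to 1409, and without replicate 4 of all groups edgeR left 21, 39, 101, 3, 99 and 0 (1820 genes at an unadjusted p under 0.05 for the last, with no other tool run).

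Gene lists whose responses differed with an estimated correlation were led by the integrated stress response. It was higher in T24 than in TCC-SUP (adjusted p = 0.000357) and CLS-439 (0.0119), and higher in 5637 than in TCC-SUP (0.0332). NF-kB genes were higher in T24 than in TCC-SUP (0.00853) and CLS-439 (0.0119), AP-1 genes higher in T24 than in CLS-439 (0.0288), and G1/S genes higher in 5637 than in CLS-439 (0.0301). Cholesterol synthesis genes were lower in T24 than in CLS-439 (0.0365), and lower in 5637 than in TCC-SUP (0.0332) and CLS-439 (0.0301).

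The 6 CLS-439 libraries stood apart in mitochondrially encoded reads (at most 0.0283%) and in processed pseudogenes. A loss of mitochondrial transcripts alone is argued against by the lowest pseudogene share of 2.75%, above the highest of 0.229% in the other libraries. The 2 CLS-439 libraries at least as deep as the shallowest other (19384501 reads) had a mitochondrial share of at most 0.027%. A share of reads is not expected to change with depth, so this comparison is no test of depth. RNA whose sequence differs from the human reference stays open: 35 protein-coding genes at 10 CPM or more in the other lines were under 0.1 CPM in CLS-439, against 9, 4 and 15 for T24, 5637 and TCC-SUP treated alike, which met neither bound set for that test. A second test was added after this first result, on 4 gene copies found in humans alone. They held 0.619% to 0.754% of the reads of their parent genes in CLS-439 and 3.24% to 6.77% elsewhere. All CLS-439 values lay below the others, but not each far enough below to reach the bound for a differing sequence. This test too met neither bound. Protein-coding mitochondrial genes held 0.00447% to 0.00882% of the reads in CLS-439 and 2.80% to 5.07% elsewhere. Most mitochondrial reads in CLS-439 therefore lay in non-coding mitochondrial genes, while in the other lines most lay in coding ones. What this split means for the sequence was not tested. Correlations between libraries were 0.68 to 0.76 for CLS-439 with the other lines and 0.83 to 0.91 among the other lines. A difference between the lines themselves was not tested and stays open as well, and the identity of this line should be checked from reads, which were not used here.

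CLS-439 also had few called genes after MMC, 129 against 4306 or more. Depth as the whole cause is argued against by 3943 calls in TCC-SUP, the lowest other line, when every library was thinned to the depth of the shallowest library (13791428 reads), where CLS-439 had 118. A spread estimated over all lines is argued against as the whole cause by fits of a line alone, which gave 673 calls in CLS-439 and 3570 or more in the others. Genes read poorly in this line are argued against by the 7368 genes at 10 CPM or more in all groups, whose log2 fold changes had an SD of 0.209 in CLS-439 and 0.452 to 0.538 in the others. A smaller response of these cells to the drug may account for the pattern, which was not tested apart from the open question of the sequence.

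Genes lower after MMC had longer genomic spans. A candidate explanation is that crosslinks block transcription of long genes, which predicted a Spearman's rho of log2 fold change with span at or below -0.15: it was -0.161 in T24, -0.227 in 5637 and -0.302 in TCC-SUP over 20792 genes (single replicates -0.219 to -0.107, -0.287 to -0.124 and -0.361 to -0.216, the first 2 ranges on both sides of that bound), and -0.274, -0.309 and -0.394 over the 12373 genes at 10 CPM or more. In CLS-439 rho was -0.006 over all genes, 0.036 over the second set and -0.091 after the ranks of exon length, GC content and expression level were removed, with single replicates from -0.109 to 0.118, which decides nothing there. Exon length, GC content and expression level are argued against as the cause in TCC-SUP, where rho was -0.256 after the same step, while values of -0.089 in T24 and -0.134 in 5637 lay between the bounds and leave them open. These correlations are across genes, which are not independent replicates.

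Other splits of the libraries into groups of the same size were counted for each comparison with edgeR alone. For the response in a line there are 10 splits, too few for a share under 0.05. The real counts were 5947, 6128, 4306 and 129 in T24, 5637, TCC-SUP and CLS-439, and the highest other splits gave 1599, 0, 3 and 0 calls (5133, 3154, 2615 and 1200 genes at an unadjusted p under 0.05, against 7928, 8137, 6823 and 1623 for the real ones). In each line 1 of the 10 splits gave as many calls, the real one. The T24 split with 1599 calls set untreated replicates 1 and 3 with treated replicate 1 against the rest. In 5637 and CLS-439, where the numbers were taken as pairs, 4 of the 10 splits part every pair, the real one among them. The other splits of these lines gave 0 calls whether or not they parted every pair.

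For the mean response, the differences between lines and the untreated lines, 1 of 60 splits gave as many calls, the real one. The splits were drawn so that no line kept its own labels. For the untreated lines chance can be excluded only for the case that all 4 lines were alike. Those splits mix lines within a group, which adds to the spread and can lower their counts, so they do not test a single line. For the mean response the splits treat the lines as independent, though same-numbered treated libraries of T24, 5637 and TCC-SUP deviated together (correlations from 0.21 to 0.69), so they cannot exclude chance. For differences between lines these splits also break the treatment effect, which adds to the spread and can lower their counts, so they cannot exclude chance there. The highest other splits gave 685 calls for T24 and 5637, 379 for T24 and TCC-SUP, and 4245, 4204, 4009 and 4966 for untreated T24, 5637, TCC-SUP and CLS-439. At an unadjusted p under 0.05 the highest other splits had 4651 genes for T24 and 5637 and 4125 for T24 and TCC-SUP, more than the 3378 and 3499 of the real ones. For the mean response and the other differences between lines the highest other splits gave 0 calls. At an unadjusted p under 0.05 they had 3099 genes for the mean response, 2699 for any difference among lines, 1945 for T24 and CLS-439, 2747 for 5637 and TCC-SUP, 1099 for 5637 and CLS-439, and 630 for TCC-SUP and CLS-439, against 9060, 6433, 4928, 3161, 4742 and 3555 for the real ones.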

How the results depend on the processing

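The settings without the CLS-439 libraries, those that leave out a replicate number from counts of called genes, and the counts shared by lines under each setting were chosen after the results were seen. Named genes were compared under DESeq2, another scaling, no filter, a replicate block, fits of a line alone and leaving out 1 library. No called gene reversed its direction there, and none without a call gained one in the other direction. Sign changes of genes or lists called in neither fit were not counted. Of 549 gene results DESeq2 ended 5 calls and added 1. Of 550, the scaling change ended 5 and added 1 and no filter ended 24 and added 4. Of 536, the fits of a line alone ended 43 and added 5. Of 3300, leaving out 1 library ended 490 and added 3. These totals include results without a call, which cannot lose one. Many of the genes were chosen for large changes, so these shares do not stand for other calls. Of the list results, 2 reversed, both with fry and neither called before: pro-apoptotic regulators in untreated TCC-SUP (0.000205) and p53 target genes in untreated CLS-439 (2.59e-05). The cause was not tested. An estimated correlation ended 78 of 107 list calls, fry 9, the other scaling 1 (mitochondrial biogenesis in 5637, 0.0519) and leaving out replicate numbers 6 to 8. Of 226 list results not called before, fry, which does not compare a list with other genes, added 95 and no filter 29, the block 5 and leaving out replicate numbers 2 to 6. Another scaling moved the median of all genes by over 0.1 from 0 in untreated T24 (-0.129 with DESeq2 and -0.121 with its factors in edgeR) and untreated CLS-439 (0.101).

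A minimum log2 fold change of 1 left 1533 higher and 1090 lower genes in T24, 1779 and 1251 in 5637, 710 and 1135 in TCC-SUP, 41 lower in CLS-439, 846 and 608 for the mean response, 478 for T24 and 5637, 524 for T24 and TCC-SUP and 1224 for T24 and CLS-439. In the untreated comparisons it left 2812 and 3066 in T24, 3875 and 3200 in 5637 and 2712 lower in TCC-SUP. Fewer genes can pass a fold minimum by its construction. Fitted alone, T24 gave 1907 and 1663 and CLS-439 gave 292 and 381. DESeq2 gave 119 higher and 157 lower in CLS-439, 1424 for T24 and 5637, 1379 for T24 and TCC-SUP, 1060 for 5637 and TCC-SUP, 1343 for TCC-SUP and CLS-439, and 29 higher and 42 lower in every line. No filter gave 116 and 216 in CLS-439, 870 for 5637 and TCC-SUP, 1235 for TCC-SUP and CLS-439, and 91 lower in every line. Without the CLS-439 libraries 937 genes differed among the lines, 456 for T24 and 5637 and 484 for T24 and TCC-SUP. For these the cause was not tested.

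At genes of 10 CPM or more, and then with no filter, Pearson's r was 0.647 and 0.306 for T24 and 5637, 0.566 and 0.24 for T24 and TCC-SUP, 0.666 and 0.282 for 5637 and TCC-SUP, 0.199 and 0.042 for T24 and CLS-439, 0.272 and 0.057 for 5637 and CLS-439, and 0.291 and 0.049 for TCC-SUP and CLS-439. Spearman's rho was 0.659 and 0.356, 0.608 and 0.298, 0.676 and 0.324, 0.246 and 0.086, 0.335 and 0.111, and 0.329 and 0.103 for the same pairs. The sets of genes differ by construction.

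The replicate block gave 113 lower genes in CLS-439, 835 for TCC-SUP and CLS-439, and 39 lower in every line. In T24 and TCC-SUP, where replicate numbers were not taken as pairs (same-numbered correlations 0.46, -0.23 and 0.52, and 0.09, -0.03 and -0.25), the block gave 3253 higher and 3190 lower, and 2265 and 2695, and it added calls of danger signals (0.049) and ribosomal protein genes (0.0256) in T24. In 5637, where the numbers were taken as pairs, POR, ERCC8, NAIP and EGLN3 lost their calls with log2 fold changes of 0.40, -0.42, -1.42 and 1.10. It changed no other call of a named gene or list in 5637 and CLS-439 than those given here and beside the results.

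Leaving out 1 library or 1 replicate number gave these lowest and highest counts. T24 had 820 to 3610 higher and 753 to 3613 lower. 5637 had 1017 to 3774 higher and 875 to 3842 lower. TCC-SUP had 100 to 2830 higher and 173 to 3381 lower. CLS-439 had 3 to 109 higher and 0 to 192 lower. The mean response had 1947 to 4363 higher and 2048 to 4248 lower, and 94 to 5085 genes differed among lines. Between pairs, the counts were 21 to 1138 for T24 and 5637, 39 to 1348 for T24 and TCC-SUP, 101 to 3063 for T24 and CLS-439, 3 to 1144 for 5637 and TCC-SUP, 99 to 3110 for 5637 and CLS-439, 0 to 1968 for TCC-SUP and CLS-439. Shared calls were 1 to 26 higher and 0 to 93 lower in every line, and 47 to 1283 and 69 to 1551 in T24, 5637 and TCC-SUP. Correlations moved beyond their spread were Pearson's r (0.253 to 0.408) and Spearman's rho (0.32 to 0.482) of T24 and TCC-SUP and Pearson's r (0.314 to 0.464) of 5637 and TCC-SUP. With CLS-439, Pearson's r was 0.061 to 0.123 for T24, 0.079 to 0.137 for 5637 and 0.087 to 0.137 for TCC-SUP, and Spearman's rho was 0.059 to 0.221, 0.147 to 0.215 and 0.127 to 0.222. The lowest counts of calls came without replicate 4 and most of the highest without replicate 1, where fewer libraries remain. Where edgeR gave 0 calls without replicate 4, 436 genes were lower in CLS-439 and 1820 differed between TCC-SUP and CLS-439 at an unadjusted p under 0.05, and no other tool was run with that setting.

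Single libraries moved differences between pairs by over 1.5 times as follows. For T24 and 5637 the count was 435 without T24 untreated replicate 1, 1138 without T24 treated replicate 1, 448 without T24 untreated replicate 3, 440 without T24 treated replicate 4, 402 without 5637 untreated replicate 1, 413 without 5637 untreated replicate 3, 431 without 5637 treated replicate 4. For T24 and TCC-SUP the count was 499 without T24 untreated replicate 1, 462 without T24 untreated replicate 3, 462 without T24 untreated replicate 4, 468 without T24 treated replicate 4, 360 without TCC-SUP untreated replicate 4, 391 without TCC-SUP treated replicate 4. For T24 and CLS-439 the count was 1336 without T24 untreated replicate 4, 1402 without CLS-439 treated replicate 1. For 5637 and TCC-SUP the count was 849 without T24 treated replicate 1, 366 without 5637 untreated replicate 1, 302 without 5637 untreated replicate 3, 331 without 5637 untreated replicate 4, 318 without 5637 treated replicate 4, 332 without TCC-SUP untreated replicate 1, 333 without TCC-SUP untreated replicate 4. For 5637 and CLS-439 the count was 2829 without 5637 treated replicate 1, 1215 without 5637 untreated replicate 3, 1192 without 5637 treated replicate 3, 1221 without 5637 untreated replicate 4. For TCC-SUP and CLS-439 the count was 1091 without T24 treated replicate 1, 925 without 5637 treated replicate 1, 180 without TCC-SUP untreated replicate 1, 1409 without TCC-SUP treated replicate 1, 220 without TCC-SUP untreated replicate 3, 114 without TCC-SUP treated replicate 3, 173 without TCC-SUP untreated replicate 4, 213 without TCC-SUP treated replicate 4, 173 without CLS-439 untreated replicate 1, 219 without CLS-439 treated replicate 1, 148 without CLS-439 untreated replicate 3, 352 without CLS-439 treated replicate 3, 198 without CLS-439 untreated replicate 4, 181 without CLS-439 treated replicate 4. Genes higher in every line numbered 20 without T24 treated replicate 1, 7 without 5637 untreated replicate 3, 7 without TCC-SUP treated replicate 4, 2 without CLS-439 untreated replicate 1, 4 without CLS-439 untreated replicate 3, 4 without CLS-439 treated replicate 3, 2 without CLS-439 untreated replicate 4, 1 without CLS-439 treated replicate 4. Genes lower in every line numbered 57 without T24 treated replicate 1, 36 without 5637 treated replicate 1, 11 without CLS-439 untreated replicate 1, 11 without CLS-439 untreated replicate 3, 6 without CLS-439 treated replicate 3, 11 without CLS-439 untreated replicate 4, 8 without CLS-439 treated replicate 4. Genes higher in T24, 5637 and TCC-SUP numbered 558 without TCC-SUP untreated replicate 3, 498 without TCC-SUP treated replicate 3.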

Other observations

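The tests of shared calls between CLS-439 and the other lines were made after the results were seen. Of the 62 genes higher in CLS-439 after MMC, 18 were also higher in T24, 21 in 5637 and 16 in TCC-SUP, and 35 in no other line. Of the 67 lower genes, 32, 39 and 36 were also lower in T24, 5637 and TCC-SUP, and 18 in no other. Independent lists of these sizes would share 9.4, 9.8 and 5.9 higher genes and 9, 9.1 and 7.4 lower genes. That reference ignores how well each gene can be called, so it sets no chance level. IL1B, an inflammatory cytokine, went from 86.5 ± 12.2 to 392 ± 58.0 CPM in T24 (log2 fold change 2.18, SE 0.23). GDF15, a stress-induced growth factor, had a log2 fold change of 2.02 (SE 0.43) in T24. The responses of both genes differed among the lines (edgeR adjusted p = 0.00357 for IL1B and 0.0115 for GDF15), so these T24 values do not stand for the other lines.

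Same-numbered treated libraries deviated from their group means in a similar way in T24, 5637 and TCC-SUP, most of all replicate 1. Across genes, the correlation of these deviations for treated replicate 1 was 0.69 between T24 and 5637, 0.57 between T24 and TCC-SUP, and 0.59 between 5637 and TCC-SUP, against -0.11, 0.06 and 0.12 with CLS-439. Treated replicate 3 gave 0.54, 0.21 and 0.54 for the first 3 pairs, treated replicate 4 gave 0.28, 0.32 and 0.35, and untreated replicate 1 gave 0.27, 0.19 and -0.03. With CLS-439, treated replicate 3 gave -0.04, 0.20 and 0.34 for T24, 5637 and TCC-SUP, and treated replicate 4 gave -0.08, 0.04 and -0.25. The SD over genes of log2 differences from the untreated mean was smallest in treated replicate 1 in these lines. For treated replicates 1, 3 and 4 it was 0.718, 0.866 and 0.766 in T24 and 0.623, 0.868 and 0.788 in 5637. The values were 0.448, 0.762 and 0.655 in TCC-SUP, and 0.367, 0.349 and 0.319 in CLS-439, where replicate 1 had the largest. The cause was not tested. In TCC-SUP the mitochondrially encoded share of reads was 4.78% ± 0.40 untreated and 6.37% ± 1.00 treated (SD, n = 3), and this difference was not tested. The share in the protein-coding mitochondrial genes was 4.53%, 4.44% and 3.93% in untreated and 4.40%, 5.07% and 4.80% in treated replicates 1, 3 and 4. The list of 13 mitochondrially encoded transcripts was not called in TCC-SUP after MMC (camera adjusted p = 0.667, median log2 fold change -0.09).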
